A study of Mus musculus with 8 samples.

How the data were processed

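Gene expression was measured on 8 single-colour Affymetrix mouse exon arrays, each hybridised with biotin-labelled cDNA amplified from total RNA of cultured murine mesenchymal stem cells, per the labels' protocols. The authors deposited 1 table of log2 expression values, with 1 row per gene and 1 column per array. The deposited values were made with RMA, per the submitters' processing notes. RMA corrects the background, brings the arrays to a common distribution of probe signals and summarises the probes of a gene on the log2 scale. The version of RMA, the definition of the probe sets, the annotation release and any filter on genes are not given in the sources used here. The quartiles of the 8 columns differed by at most 0.001, which leaves overall differences in signal between arrays out of reach of any comparison. Scanner files, scan dates and detection calls were not used here, so no batch could be tested and the signal over background of a gene is unknown. The number of arrays, 4 per group, limits the precision.

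The rows carry Ensembl mouse gene identifiers, and none of the 17592 rows could be matched to a gene symbol, because the RefSeq gene table used here (assembly GRCm38.p6) lists no Ensembl identifiers. The files do not pair the identifiers with names. Genes are therefore given by identifier, limited to the 2 with the largest rise and the 2 with the largest fall among genes past the threshold. Chromosomal positions are not given for the same reason. A rule for naming genes by symbol and 29 lists of gene symbols (pathways, differentiation programmes and markers of stromal, haematopoietic, endothelial and epithelial cells) had been fixed before the data were examined and could not be applied. In their place, 4 lists of Ensembl identifiers were built from the mouse cell-cycle marker pairs that accompany the scran package. These pairs were derived from sorted mouse embryonic stem cells. The G2/M-high, S-high and G1-high lists hold genes that were always the higher member of at least 10 pairs of that phase, and the G1-low list holds genes that were always the lower member of at least 10 G1 pairs. The lists were chosen after the rows were found to carry no names and before any comparison was computed.

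Arrays were grouped by their titles. Groups were compared with limma 3.58.1 in R 4.3.3 (linear model per gene, empirical Bayes moderation with default settings, two-sided), using all 8 arrays, all 17592 genes, no filter on dim genes and no covariate. A gene was called at a Benjamini-Hochberg adjusted p below 0.05. Gene lists were tested with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation and with fry. For each list, a score per array was the mean over its genes of the log2 value minus the gene's mean over the 8 arrays. Scores were compared by an exact two-sided permutation test over the 70 relabellings, for which the smallest possible p is 0.029. The 95% intervals of score differences hold the shifts that this test did not reject. Figures were drawn with matplotlib 3.10.9.

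The fit was tested on simulated data with the means and the moderated variances of the real genes, without deviations shared between genes. In each of 20 runs, 200 of 17592 genes were changed between 4 and 4 arrays, and 60 others were shifted by -0.1 as a list. The fit recovered 24.3% of genes changed by 0.25 on the log2 scale, 81.3% of those changed by 0.5 and 96.9% of those changed by 1. Of its calls, 5.6% were unchanged genes. A list of 60 genes shifted by -0.1 was called lower by camera in 20 of 20 runs, and an unshifted list in 0 of 20, with genes simulated as independent.

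No 2 arrays held identical values. The root mean square difference between 2 arrays of a group ranged from 0.183 to 0.241 on the log2 scale. Nothing in the labels says whether the arrays of a group came from separate cultures or animals, so p-values measure the spread between these samples, which may be technical. The alternatives tried were quantile normalization, median centring, an intensity trend or robust moderation in limma, filters on dim genes, array weights, the replicate number as a block, each array left out in turn, other thresholds and other list settings.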

Results

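Expression of 17592 genes was measured in mesenchymal stem cells of mouse bone marrow, multipotent stromal cells that were expanded in culture to passage 10. The strain is given as C57B6/J. Ropivacaine is an amide-type local anaesthetic that blocks voltage-gated sodium channels. The study had 2 groups of 4 arrays, cells exposed to ropivacaine for 24 h and untreated cells collected at the same time. The dose is 100 uM in the sample annotation, while the treatment protocol in the labels gives 100 mM, and the micromolar value was taken as the dose here. The log2 values had a median of 6.91 on every array and ran up to 13.89. Correlations between arrays across genes ranged from 0.990 to 0.995.

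The first question was which genes differed between ropivacaine-treated and untreated cells. After 24 h, 71 genes were called, 50 higher and 21 lower with ropivacaine (limma, Benjamini-Hochberg adjusted p below 0.05). The changes were modest: the median log2 fold change was 0.36 among genes called higher and -0.33 among genes called lower. The largest rise among called genes was 0.94 and the largest fall was -0.87. Among the called genes, 14 changed by at least 0.5 on the log2 scale, and 0 changed by 1 or more. In all 71 called genes, the 4 ropivacaine values lay entirely on one side of the 4 control values. Such separation was seen in 1178 of all genes, or 6.70%, against 2.86% by chance.

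**Figure D1:**
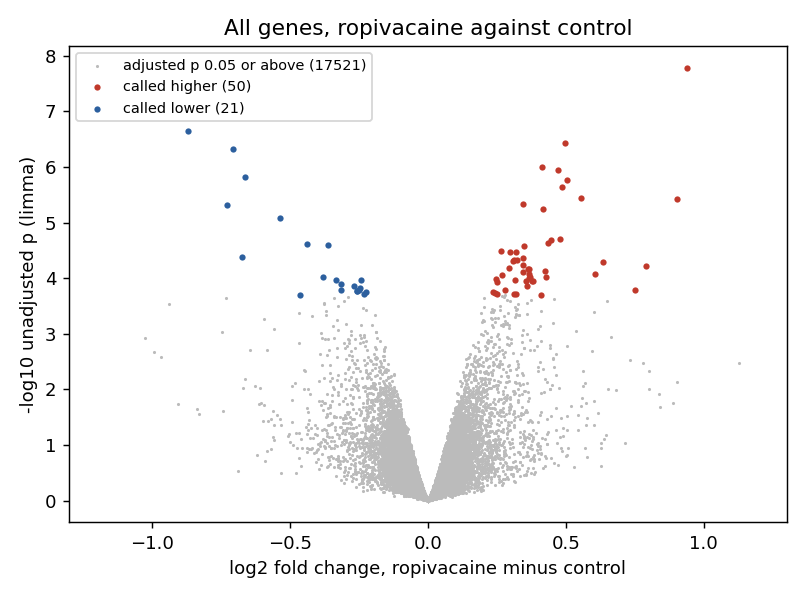
Each point is 1 of 17592 genes, placed by its log2 fold change (ropivacaine minus control, x axis) and the -log10 of its unadjusted limma p (y axis). The 50 genes called higher (red) and the 21 called lower (blue) all lie within 1 log2 unit of no change.

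The gene with the largest rise was ENSMUSG00000031762, which was also the gene with the smallest p. Its log2 expression was 10.16 ± 0.08 (SD, n = 4) in untreated cells and 11.10 ± 0.02 (SD, n = 4) with ropivacaine. This is a 1.92-fold higher level, with a log2 fold change of 0.94 (SE 0.05) and a limma adjusted p of 2.87e-04. ENSMUSG00000049723, a dimmer gene, rose from 5.79 ± 0.07 to 6.69 ± 0.18 (SD, n = 4 each). Its log2 fold change was 0.90 (SE 0.09), with a limma adjusted p of 0.0059. The control mean lies close to the first quartile of the arrays, 5.73, and whether it exceeds background is unknown, so no linear fold is given. The 4 ropivacaine arrays of this gene ranged from 6.45 to 6.86, above the highest control value of 5.85.

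The gene with the largest fall was ENSMUSG00000039883, with 8.54 ± 0.11 in untreated cells and 7.67 ± 0.05 with ropivacaine (SD, n = 4 each). Its log2 fold change was -0.87 (SE 0.06), a 1.82-fold lower level, with a limma adjusted p of 0.0020. ENSMUSG00000073945 was next and lay near the low end of the signal range. Its log2 expression was 5.06 ± 0.07 in untreated cells and 4.33 ± 0.14 with ropivacaine (SD, n = 4 each). The log2 fold change was -0.73 (SE 0.07), with a limma adjusted p of 0.0067. Both means lie below the first quartile of the arrays, 5.73, and whether they exceed background is unknown, so no linear fold is given. These 4 genes were called again when any single array was left out. Without both control replicate 2 and ropivacaine replicate 3, the arrays of lowest estimated weight, ENSMUSG00000073945 was not called (limma adjusted p = 0.056) and the other 3 genes were. With the replicate number as a block, ENSMUSG00000049723 (limma adjusted p = 0.051) and ENSMUSG00000073945 (limma adjusted p = 0.138) were not called. The genes with the largest rise and the largest fall were called in that fit.

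**Figure D2:**
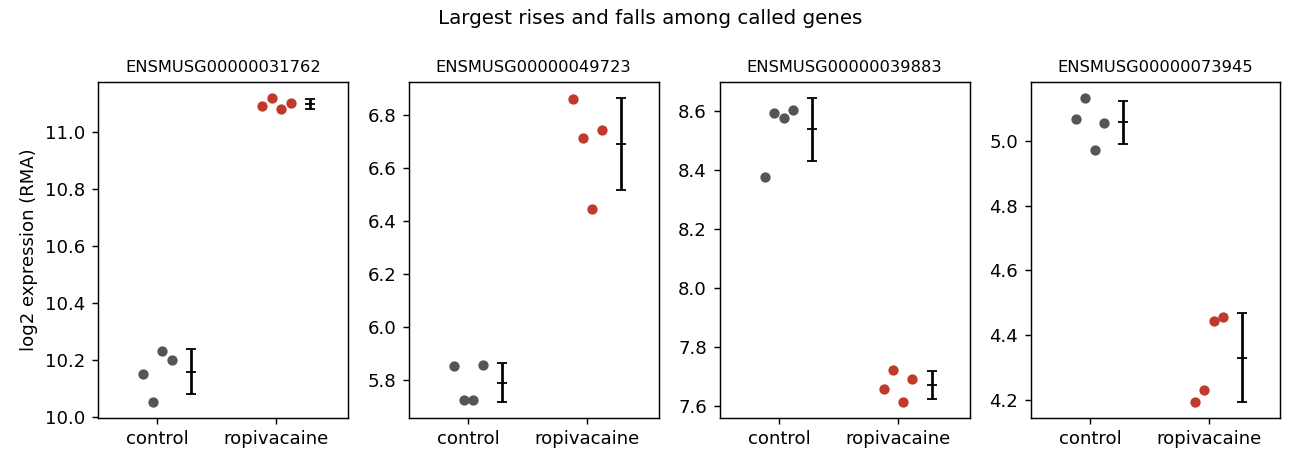
Log2 expression (y axis) of the 2 called genes with the largest rise and the 2 with the largest fall, each panel on its own scale. Dots are single arrays (4 control in grey, 4 ropivacaine in red), and the mark with whiskers beside them is the mean ± SD. In each panel the 4 treated arrays lie apart from the 4 control arrays.

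Most called genes were bright. Of the 71, 36 lay in the brightest 25% of genes by mean signal, 24 in the next 25%, 6 in the following 25% and 5 in the dimmest 25%. The median standard error of the log2 fold change was 0.05 in the brightest 25% and 0.08 in the dimmest 25%. Genes called higher and lower had similar mean signals, with medians of 8.46 and 8.56. Genes called higher outnumbered those called lower (exact two-sided binomial test against an even split, p = 7.67e-04, which treats genes as independent). The genes share the same 8 arrays, so this p does not measure how the excess would vary between cultures. Among the 14 called genes that changed by at least 0.5, 8 were higher and 6 lower. When changes were tested against 0.2, 3 were higher and 3 lower, and with the replicate number as a block, 1 was higher and 2 lower. With 1 array left out, 62.5% to 76.2% of the called genes were higher.

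At an unadjusted limma p below 0.05 there were 1714 genes, 939 higher and 775 lower, where 880 would be expected by chance. From the distribution of p-values, 89.6% of genes were estimated to be unchanged. A split that mixes the groups set control replicate 1 with ropivacaine replicates 1, 2 and 4. It reached 2386 genes at that unadjusted p and an estimate of 80.1%, although most other splits gave higher estimates. Neither value of the real split can therefore be read as the share of genes that responded to ropivacaine. The number of called genes fell to between 15 and 31 when any 1 of the 8 arrays was left out. Of the 71 genes, 14 were called in every one of these fits, 10 higher and 4 lower. The lowest count, 15, was obtained without control replicate 3, and the highest, 31, without ropivacaine replicate 3.

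The second question was whether genes that mark phases of the cell cycle shifted with ropivacaine, since effects of local anaesthetics on stem cell growth were an interest of the study. None of the 4 marker lists was called as shifted. Membership of a list ranks a gene against its partners in the pairs and does not give its own level across phases. The G2/M-high list comes from pairs for cells preparing for or undergoing division. It had 60 measured genes with a median log2 fold change of -0.02 (camera p of 0.13, adjusted p = 0.27). Of these, 0 rose and 0 fell, and 18 of the 60 had a positive log2 fold change. The G1-low list, whose genes were always the lower member of their G1 pairs, had 52 measured genes and a median of -0.02 (camera p of 0.14, adjusted p = 0.27). Again 0 rose and 0 fell, and 18 of the 52 were positive. These lists share 31 genes and are not independent. The G1-low list also shares 19 genes with the S-high list, which shares 8 with the G2/M-high list.

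The S-high list held 71 measured genes, of which 0 rose and 1 fell (median log2 fold change -0.01, camera p of 0.62, adjusted p = 0.62). The G1-high list held 58 measured genes, of which 1 rose and 0 fell (median -0.01, camera p of 0.42, adjusted p = 0.56). Adjusted over the list alone, 1 gene fell in the S-high list, 1 rose and 1 fell in the G1-high list, and 0 passed in the other lists. With an estimated correlation, the adjusted p was 0.55 for the G2/M-high and G1-low lists and 0.79 for the S-high and G1-high lists. The corresponding fry adjusted p-values for a shift in one direction were 0.34, 0.34, 0.70 and 0.67. Across all 667 marker genes in the pairs, 638 were measured and 3 were called, 2 higher and 1 lower. This share of 0.470% compares with 0.401% of the other genes (Fisher's exact test, two-sided, p = 0.74).

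The score of the G2/M-high list was 0.008 ± 0.011 in untreated cells and -0.008 ± 0.023 with ropivacaine (SD, n = 4 each). The difference of -0.015 had a 95% interval of -0.058 to 0.016 (exact permutation test, two-sided, p = 0.29). For the G1-low list the difference was -0.016, with an interval of -0.057 to 0.017 (exact permutation test, two-sided, p = 0.29). Most of both differences came from ropivacaine replicate 3. Without it they were -0.004 and -0.005 (exact permutation p = 0.60 and 0.54). The S-high difference was -0.004 (interval -0.074 to 0.044, exact p = 0.83) and the G1-high difference was -0.007 (interval -0.045 to 0.037, exact p = 0.66). Adjusted over the 4 lists, the exact permutation p-values were 0.57 for G2/M-high and G1-low and 0.83 for the others.

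**Figure D3:**
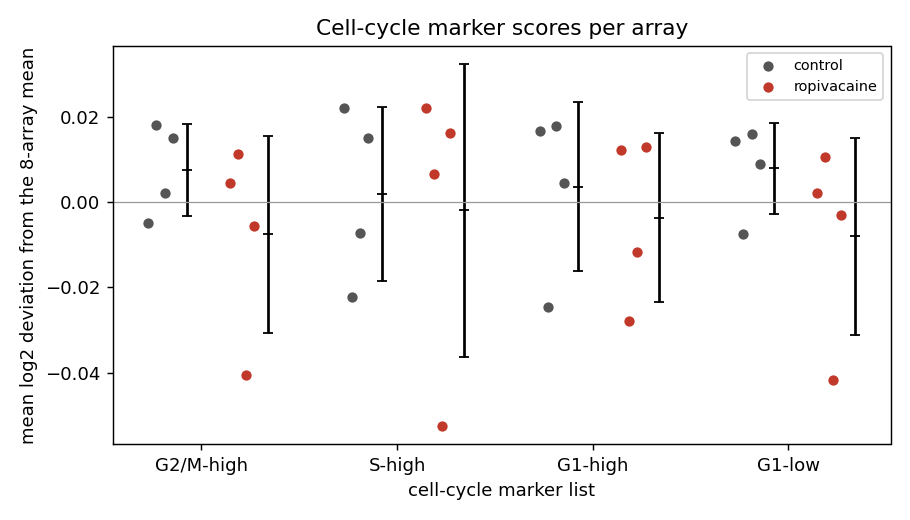
Mean log2 deviation of each cell-cycle marker list from its mean over the 8 arrays (y axis), by list (x axis). Dots are single arrays (control in grey, ropivacaine in red), and the mark with whiskers beside them is the mean ± SD of 4 arrays. The groups overlap in every list.

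The groups overlapped along the direction of largest variance. The first principal component held 26.3% of the variance, with means of 5.11 for control and -5.11 for ropivacaine arrays (exact permutation test, two-sided, p = 0.20, adjusted over 2 components p = 0.20). Control replicate 2 lay farthest out, at 18.7, and ropivacaine replicate 3, at 6.57, lay on the same side. The second component held 15.6% of the variance and separated all 4 control from all 4 ropivacaine arrays. Its exact permutation p was 0.029, the smallest this design allows, and 0.057 after adjustment over the 2 components. Control replicate 2 also had the lowest estimated array weight, 0.580, followed by ropivacaine replicate 3 with 0.708. Without both arrays, 7 genes were called, 4 higher and 3 lower, and all 7 were among the 71.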

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

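One value stood apart from the other arrays of its group. For ENSMUSG00000039883, the gene with the largest fall, control replicate 1 had a log2 expression of 8.38, while the other control arrays lay between 8.58 and 8.61. The gap to the nearest array was 0.882 of the group's range, above the 95% critical value of Dixon's test for 4 samples. This test was made on 22 sets of 4 values, and chance gives about 1 in 20. Without this array the log2 fold change of the gene was -0.92 and its limma adjusted p was 9.15e-04.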

How the results depend on the processing

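The count of called genes was 71 under quantile normalization, median centring and robust moderation, with the 71 genes shared in each, and 105 with array weights. The first 2 settings move little, because the deposited values already have equal quartiles. It rose to 135 with an intensity trend in limma, to 114 without the dimmest 25% of genes and to 179 without the dimmest 50%, where fewer genes were tested. It was 15 at an adjusted p below 0.01, 14 with a log2 fold change of at least 0.5, and 6 when changes were tested against 0.2. Leaving out 1 array gave 15 to 31 genes, and leaving out both arrays of lowest weight (chosen after seeing the data) gave 7. With the replicate number as a block, 3 genes were called, 1 higher and 2 lower, all among the 71, and 1715 genes had an unadjusted p below 0.05 against 1714 without the block. The main fit had no block because no pairing is stated. Same-numbered arrays deviated from their groups with correlations of 0.138, 0.009, 0.056 and 0.070. Of 8 arrays, 4 correlated best with their own number. These values do not settle whether the numbers pair the arrays, because deviations within a group sum to zero. The fit with the block is therefore not set aside. The block left the log2 fold changes as they were, and the adjusted p of ENSMUSG00000049723 became 0.051 and that of ENSMUSG00000073945 0.138. For ENSMUSG00000073945 it was 0.056 without both arrays of lowest weight. The other 62 of 65 values of the 4 genes under the alternatives stayed past the threshold. The share called higher was 70.4% under both scalings, which move little, but 57.1% (8 of 14) at a log2 fold change of at least 0.5, 50% (3 of 6) when tested against 0.2, 57.1% (4 of 7) without both arrays of lowest weight and 33.3% (1 of 3) with the block. No cell-cycle list was called under any alternative. The S-high list changed direction in 3 of them. The camera p was 0.977 without control replicate 4, 0.572 without ropivacaine replicate 3 and 0.962 without both arrays of lowest weight. Over all fits with a single array left out, reversed or not, the camera p of this list ranged from 0.289 to 0.996. The cause of these changes was not tested. Choosing rows with 1 gene symbol, averaging the rows of a gene and the lists of gene symbols could not be run, because the rows carry no symbols and each gene has 1 row. Without scanner signals, the limit set by background is unknown.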

Other observations

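Of the tests in this part, the brightness of the called genes and the deviations shared by control replicate 2 and ropivacaine replicate 3 were chosen after the result was seen.

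The 71 called genes were set against every other way of splitting the 8 arrays into 4 and 4. Only the real split, 1 of 35, called as many genes, and the highest count of any other split was 0. This is the smallest share that 35 splits allow. It argues against a chance split for the count of called genes but cannot exclude one. The argument does not extend to the count at an unadjusted p below 0.05. There, 2 of the 35 splits, the real one included, reached 1714 genes. Most calls were not of dim genes, since 7.04% of the called genes lay in the dimmest 25% of genes (Fisher's exact test, two-sided, p = 1.58e-04, against 25% for all genes). That p does not show that dim genes changed less. Their median standard error was 0.08, against 0.05 in the brightest 25%, which makes a call less likely. Which genes lie near background is unknown. A difference in culture handling or array processing that followed the groups stays open, because no batch is given.

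A different split had more genes at an unadjusted p below 0.05 than the real one. It set control replicate 1 with ropivacaine replicates 1, 2 and 4 against control replicates 2, 3 and 4 with ropivacaine replicate 3, and reached 2386 genes against 1714, although 0 of them passed the adjusted threshold. These sides are those of the first principal component, so both describe the same direction of variance in these arrays. Over the 31 genes called without ropivacaine replicate 3, its median position was 0.804 on a scale from 0 at the control mean to 1 at the ropivacaine mean. That argues against ropivacaine replicate 3 alone being a control array. It cannot decide an exchange of labels with control replicate 1, which counted as a control when these genes were chosen. Control replicate 2 as a treated array is argued against in the same way (median position 0.046 over 22 genes), and its larger deviation was not limited to dim genes, being 1.39 times that of the other control arrays in the brightest 25% of genes. A technical difference shared by control replicate 2 and ropivacaine replicate 3 stays open, as does a difference between cultures, which was not tested. Their deviations correlated at 0.219, which decides nothing, because deviations within a group sum to zero and the other pairs give no independent chance level.

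A hypothesis tested here was that ropivacaine lowered the markers of cycling cells. The G1-low list gave a camera p of 0.135 with a negative median, so the predicted shift was not found. A p above the threshold was set beforehand as evidence against the hypothesis, which was too strict a reading. The 95% interval of the score difference, -0.057 to 0.017, still allows a small fall, while a uniform fall of 0.1 lies outside it. The lists come from embryonic stem cells, and a mean over marker transcripts may miss a change in the share of cycling cells that these lists do not follow.

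Genes of the G1-high list gave a small fry p for change in either direction (1.66e-06, adjusted 6.65e-06), in contrast to its p for one direction (0.50). Of its 58 genes, 9 had an unadjusted limma p below 0.05, 3 higher and 6 lower, or 15.5% against 9.72% of the other genes (Fisher's exact test, two-sided, p = 0.177). Among 1000 random lists of the same size and brightness, 17.3% had a mixed p as small, so the small p may reflect changes spread over many genes. A response particular to this list stays open, since the interval of the odds ratio, 0.735 to 3.52, is wide.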
